A study of Mus musculus with 8 samples.

How the data were processed

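Liver RNA of 4 Per2Brdm1 mutant and 4 wild-type mice, all starved for 8 h, was measured on 1-colour Agilent arrays with 1 array per mouse. The 8 columns were grouped by the genotype in their labels, and 0 columns were left unused. The deposited values were taken as log2 values that the authors had normalised by a method that is not stated and centred on each probe's median over the 8 arrays. The log base, the scaling between arrays and the direction of the scale were not stated. Base 2 was inferred from the range of the values, and higher was taken as brighter. Because of the centring the values carry no levels, so signal over background could not be given for single genes. The number of arrays limits the precision.

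The medians of the deposited columns were 0.10, -0.05, 0.09 and 0.07 in mutant replicates 1 to 4 and -0.00026, -0.09, -0.05 and -0.09 in wild type replicates 1 to 4. The 75th percentiles differed by more than 0.1, and each array was therefore shifted to a common 75th percentile. The shifts were -0.09 to -0.01 in the mutants and 0.05 to 0.07 in wild type. The scaling thus ran with genotype and lowered every mutant minus wild type difference. Of 41252 probes, 78 control features were set aside and 41174 were tested. A single gene symbol was given for 32664 probes, several for 45 and none for 8465. Probes of the same gene were averaged, which gave 19532 named genes and 8510 rows for single probes without a single symbol, 28042 in all. Among the named genes 8511 had several probes.

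The mutant minus wild type difference was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and a row passed at a Benjamini-Hochberg adjusted p under 0.05 over all rows. Per2 was also tested per probe and with an exact permutation test over the arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The methods of the study select probes at a p under 0.05 without naming the test, and a two-sided Student test per probe was counted beside limma. A set of 31 gene lists with 524 genes, of which 474 were measured, covered clock, glycogen, glucose, lipid, bile acid and drug metabolism, sex-biased genes, inflammation, stress, cell cycle, respiratory chain and cell types. Listed genes without a matching probe were not analysed here. The 30 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Genes around Per2 were compared with all others by a two-sided Fisher's exact test over 100 measured genes on each side.

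The named genes were Per2, the 3 members of each list with the smallest p (6 for the clock and glycogen lists), and the 10 largest rises and 10 largest falls among passing genes whose groups did not overlap. Predicted genes would have been skipped, and 0 were. These tests, lists and naming rule, and the alternatives of quantile scaling, a common median, single probes, robust variance, array weights, a block for the replicate number, leaving out each mouse, other set tests and other window sizes, were chosen before the data were examined. The values as deposited, the fits without wild type replicates 2 and 3, with the control features as a covariate or without rows that follow them, and 4 further tissue lists (squamous epithelium, glandular stomach, intestine and smooth muscle) were added after seeing the data.

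The procedure was tested on simulated data with the same numbers of arrays and rows. Of 100 genes changed by 1 on the log2 scale 44 were recovered, and of 100 changed by 2 on that scale 83, all with the right sign, and of 134 calls 5 were false and 2 were members of a glycogen list that had also been shifted. With no simulated change 0 genes and 0 lists were called. The simulated rows were drawn independently of each other, so the simulation does not test list calls where genes are correlated. Besides the list, 200 of 28042 rows were changed, against 4333 rows called in the data. The recovered shares may therefore not hold for the data, as the adjusted threshold depends on how many rows change. The glycogen list, shifted by -0.5, was called, with a median of -0.49.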

Results

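Liver RNA was measured on 1-colour Agilent arrays in 4 mice carrying the Per2Brdm1 mutation and in 4 wild-type mice. All 8 animals came from 1 cohort of mixed 129sv and C57Bl/6 background and were killed after 8 h of starvation. Per2 is a core gene of the circadian clock, and the Brdm1 allele is known as a deletion within the region that encodes its protein-interaction domain. The comparison asked which liver transcripts depend on Per2, with glycogen metabolism as the stated interest. The deposited table held 41252 probes, of which 41174 were tested after 78 control features had been set aside. Each probe was centred on its own median over the 8 arrays, so the values give differences between mice and no expression levels. The log base was not stated and was taken as 2, and higher values were taken as brighter signal. All fold changes depend on these readings, and the number of arrays limits the precision. Differences below are mutant minus wild type on the log2 scale, ± the standard error of the limma fit, with 4 mice in each group and Benjamini-Hochberg adjusted p-values from that fit.

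The 2 Per2 probes moved in opposite directions in every mouse. Probe A_51_P282760 was lower in the mutants by -1.70 ± 0.12 (adjusted p = 0.000333), with a mean of -0.78 ± 0.05 (SD, n = 4) in mutants and 0.92 ± 0.19 (SD, n = 4) in wild type. Probe A_52_P536869 was higher by 2.54 ± 0.13 (adjusted p = 0.000123), with a mean of 1.27 ± 0.19 (SD, n = 4) against -1.27 ± 0.12 (SD, n = 4). For each probe the exact two-sided permutation test gave p = 0.0286, the smallest value that 4 against 4 mice allow. Averaged over both probes, as was done for all genes, Per2 differed by 0.42 ± 0.11 (adjusted p = 0.0380), a value that stands for neither probe. That averaged call was lost in 7 of the 8 fits that left out 1 mouse. The positions of the probes within the transcript were not given, and a probe outside the deleted part does not check the genotype.

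**Figure D1:**
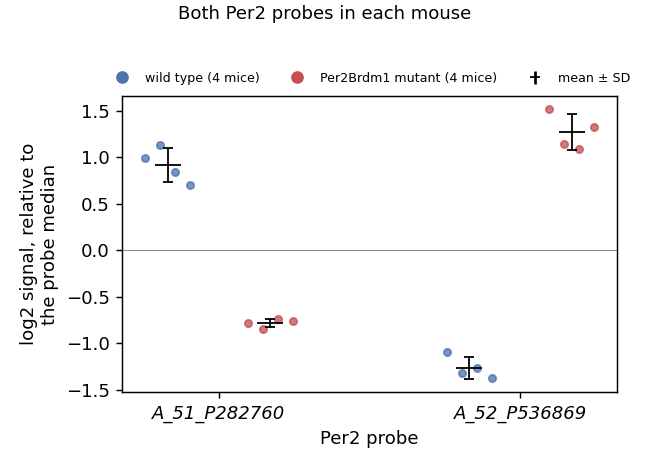
Signal of both Per2 probes in each mouse, as log2 values relative to the probe median after scaling of the arrays (vertical axis), by probe (horizontal axis), with single mice as dots and the mean ± SD of 4 mice as bars. The mutants lie near -0.78 for the first probe and near 1.27 for the second, on opposite sides of the wild-type mice.

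The livers of the mutants differed widely from those of wild-type mice. Of 19532 named genes, 1393 rose and 2048 fell in the mutants at an adjusted p under 0.05, and 674 of the former and 555 of the latter changed at least 2-fold. The largest rises included the acute phase genes Saa3, Saa2 and Saa1, the cell cycle inhibitor Cdkn1a and the chemokine Cxcl14. The largest falls were led by Crct1, Krt4 and other genes of cornified and squamous epithelium, a grouping made after the values were seen. Counting 8510 unnamed probes as well, 4333 of 28042 rows changed, with 1828 higher and 2505 lower, so that 42.2% were higher. The groups did not overlap in 24.6% of rows, against 2.86% expected by chance. The share of higher calls depended on the scaling between arrays. With the values as deposited, 2449 rows were higher and 1537 lower (61.4% higher), because that scaling moved the median difference of all rows from 0.08 to 0.20. Wild type replicates 2 and 3 had lower control features, at -0.66 and -0.43 after scaling, against -0.04 to 0.13 on the other 6 arrays. Leaving out these 2 mice reduced the genes changed between genotypes, counted as rows, to 1766, with 879 higher and 887 lower, and leaving out wild type replicate 3 alone gave 2884. Wild type replicate 1 stood apart in other ways, with correlations of -0.01 to 0.08 with the other wild-type arrays, the lowest array weight (0.60) and a second principal component of -120.1, against 0.39 to 41.9 on the other 7 arrays. Without it the rows with an unadjusted p under 0.05 rose from 8494 to 12219, and 3696 rows changed. The study selected probes at a p under 0.05 without naming the test. A test of the difference in means per probe, chosen here and named with the processing steps, gave 12340 probes under that threshold (4595 higher and 7745 lower), against 2058.7 expected by chance, and 7100 after Benjamini-Hochberg adjustment, while the form with unequal variances gave 11246 and limma per probe 12755.

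Clock genes changed in both directions. Arntl, the partner of Clock in the activating arm of the clock, rose by 3.10 ± 0.31 (8.55-fold, adjusted p = 0.00117), and Nfil3, a repressor at D-box elements, rose by 1.07 ± 0.14 (adjusted p = 0.00273). Dbp and Tef, the D-box activators, fell by 2.45 ± 0.30 and 1.36 ± 0.24 (adjusted p = 0.00233 and 0.00930). Ciart, a repressor of Clock and Arntl activity, fell by 2.22 ± 0.24 (adjusted p = 0.00145), and the deubiquitinase gene Usp2 fell by 0.87 ± 0.14 (adjusted p = 0.00638). Of the 22 measured members of the clock list, 8 fell and 5 passed as higher, 1 of which was the average of Per2's opposite probes, and 9 were lower and 6 higher when adjusted over the list alone. Besides Arntl and Nfil3, the members that rose were Clock (1.12 ± 0.27) and Cry1 (1.09 ± 0.26), named after their values were seen. Per1 differed by -0.38 ± 0.15, Per3 by 0.25 ± 0.27, Nr1d1 by 0.12 ± 0.18 and Npas2 by -0.21 ± 1.17, and none of these passed. As a whole the list did not shift against other genes (camera, adjusted p = 0.260). The count of 13, the Per2 average included, fell to 5 without the 2 mice with lower control features, where Usp2 differed by -0.83 and no longer passed (adjusted p = 0.0637), and to 7 or 8 without mutant replicate 2 or without wild type replicate 2, 3 or 4.

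Glycogen genes that changed all fell. Ugp2, which makes the UDP-glucose used for glycogen, fell by 1.72 ± 0.11 (3.28-fold, adjusted p = 0.000237). The branching enzyme gene Gbe1 fell by 1.12 ± 0.12 (adjusted p = 0.00159), and Gys2, the liver glycogen synthase, fell by 0.87 ± 0.10 (adjusted p = 0.00174). Falls were also seen for the phosphoglucomutase gene Pgm1 (-0.85 ± 0.11, adjusted p = 0.00247), for Nhlrc1, the gene of the ubiquitin ligase malin (-0.76 ± 0.12, adjusted p = 0.00596), and for Ppp1r3c, a subunit that targets protein phosphatase 1 to glycogen (-0.89 ± 0.23, adjusted p = 0.0352). Of 25 measured members 6 fell and 0 rose by the limma test, and 7 fell when adjusted over the list alone. The glycogen phosphorylase gene Pygl differed by -0.35 (adjusted p = 0.16) and Ppp1r3b, another targeting subunit, by 0.12 (adjusted p = 0.60), and neither passed. The list lay lower than other genes by camera (adjusted p = 0.000777), with adjusted p = 0.184 when the correlation between genes was estimated. Ppp1r3c passed for neither of its probes alone, and its call was lost as deposited (adjusted p = 0.0630) and without any one of the 4 mutants or wild type replicate 4.

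**Figure D2:**
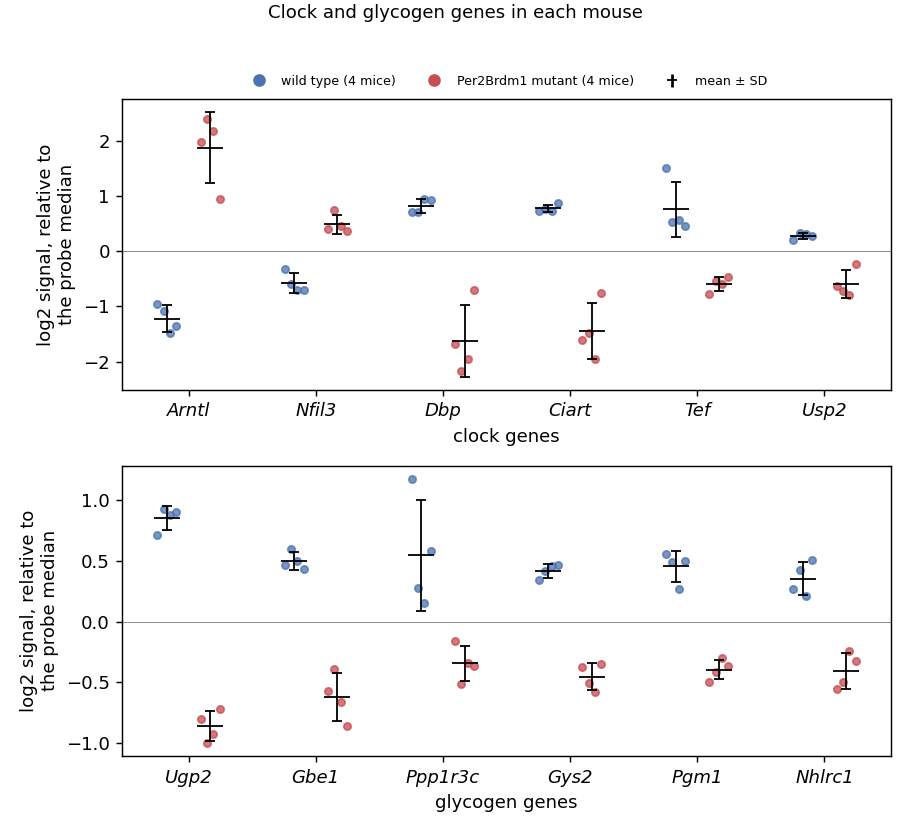
Signal of 6 clock genes (upper panel) and 6 glycogen genes (lower panel) in each mouse, as log2 values relative to the probe median after scaling of the arrays (vertical axis), with single mice as dots and the mean ± SD of 4 mice per group as bars. The groups do not overlap for any of the 12 genes: Arntl and Nfil3 are higher in the mutants, and the other 10 genes are lower.

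The genes of glucose use and lipid synthesis that passed were all lower. Of 17 measured genes of glycolysis and glucose uptake, 7 fell and 0 rose by the limma test, among them the pyruvate kinase gene Pklr (-1.96 ± 0.17), the glucose transporter gene Slc2a2 (-1.42 ± 0.17) and Gckr (-0.84 ± 0.10). Of 20 genes of fatty acid and triglyceride synthesis, 10 fell and 0 rose. The smallest limma p-values among them were those of the lipogenic regulator genes Thrsp (-2.93 ± 0.15), Srebf1 (-1.88 ± 0.20) and Mid1ip1 (-1.40 ± 0.17). Cholesterol synthesis had 8 of 19 genes lower and 0 higher, including Msmo1 (-1.35 ± 0.19), the cholesterol transfer gene Stard4 (-1.16 ± 0.14) and the mevalonate kinase gene Mvk (-1.02 ± 0.17). These 9 genes had adjusted p-values from 0.000105 to 0.00753. Adjusted over the list alone, 7 glycolytic genes fell, 16 lipogenic genes fell and 1 rose, and 13 cholesterol genes fell. By camera the 3 lists lay lower than other genes, with adjusted p = 6.01e-05, 2.61e-07 and 7.52e-06. With an estimated correlation none was called, with adjusted p = 0.193, 0.193 and 0.545.

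The lists of fasting and of fatty acid oxidation were not called, while single members changed. Igfbp1, an insulin-repressed binding protein gene, rose by 2.68 ± 0.34 (adjusted p = 0.00260) and Pdk4, which blocks pyruvate oxidation, rose by 2.21 ± 0.36 (adjusted p = 0.00674), while the alanine aminotransferase gene Gpt fell by 0.64 ± 0.12 (adjusted p = 0.0130). In the gluconeogenesis and fasting list 3 of 21 genes rose and 3 fell. The third that rose was G6pc (0.79), and the other genes that fell were Aqp9 and Gcgr (-0.65 and -0.37), all named after their values were seen. Among 22 genes of fatty acid oxidation and ketogenesis 6 rose and 1 fell. The microsomal hydroxylase genes Cyp4a14 and Cyp4a10 rose by 2.10 ± 0.26 and 1.72 ± 0.18 (adjusted p = 0.00236 and 0.00121), and Bdh1, of ketone body interconversion, fell by 0.90 ± 0.11 (adjusted p = 0.00228). Adjusted over the list alone, 3 fasting genes rose and 5 fell, and 6 oxidation genes rose and 3 fell. Neither list was called by camera (adjusted p = 0.571 and 0.599), and for the fasting list the mean (0.17) differed in sign from the median (-0.05) and from the direction of the test. Without the 2 mice with lower control features the call of Gpt was lost (adjusted p = 0.0671).

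Most of the drug metabolism, bile acid and respiratory chain genes that passed were lower. Of 26 drug metabolism genes 12 fell and 1 rose, which was Cyp3a13 (0.45), named after its value was seen. The smallest limma p-values in this list were those of the glutathione transferase genes Gsta2 (-2.01 ± 0.15) and Gsta1 (-1.04 ± 0.11) and of Aldh1a1 (-0.92 ± 0.13). Of 19 genes of bile acid synthesis and transport 5 fell and 2 rose. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.52 ± 0.31 (adjusted p = 0.0166), the uptake transporter gene Slc10a1 fell by 0.63 ± 0.10 (adjusted p = 0.00629) and the export transporter gene Abcc3 by 0.93 ± 0.18 (adjusted p = 0.0129). Amacr (-0.96) and Nr1h4 (-0.39) also fell and Cyp7b1 (1.10) and Abcb4 (0.53) rose. Of 22 respiratory chain genes 5 fell, by small amounts, among them Ndufs1 (-0.50 ± 0.11), Uqcrc2 (-0.47 ± 0.11) and Sdha (-0.41 ± 0.09), together with Ndufb8 (-0.40) and Uqcrfs1 (-0.38). Amacr, Nr1h4, Abcb4, Ndufb8 and Uqcrfs1 were named after their values were seen. Adjusted over the list alone the counts lower and higher were 16 and 3, 8 and 3, and 7 and 0. By camera the lists lay lower than other genes (adjusted p = 4.69e-06, 0.00405 and 0.000335). The calls were lost with an estimated correlation, with adjusted p = 0.193, 0.193 and 0.545. Without the 2 mice with lower control features Cyp7a1 (adjusted p = 0.138), Abcc3 (adjusted p = 0.106) and Ndufs1, Sdha and Uqcrc2 (adjusted p = 0.0857 to 0.121) no longer passed, and those 3 respiratory chain genes did not pass as deposited either. Sdha and Uqcrc2 also lost their calls without any one of mutant replicates 3 and 4 or wild type replicates 2 to 4, and Ndufs1 without mutant replicate 2 (adjusted p = 0.0508 to 0.0723).

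The serum amyloid genes rose most among the acute phase genes. Saa3 rose 18.4-fold (standard error 0.23 on the log2 scale, adjusted p = 0.000143), Saa2 by 4.17 ± 0.17 (17.9-fold, adjusted p = 5.57e-05) and Saa1 by 4.03 ± 0.19 (16.3-fold, adjusted p = 9.40e-05). Of 27 measured acute phase and inflammation genes 7 rose and 1 fell, which was Hamp2 (-3.22, named after its value was seen), and 8 rose and 1 fell when adjusted over the list alone. The list lay higher by camera (adjusted p = 0.00273), with adjusted p = 0.193 with an estimated correlation. Of 18 interferon response genes 4 rose and 2 fell, with 6 and 5 over the list alone. The interferon regulator gene Irf7 rose by 1.46 ± 0.11 (adjusted p = 0.000416), and the oligoadenylate synthetase-like genes Oasl2 and Oasl1 rose by 1.15 ± 0.18 and 0.78 ± 0.15 (adjusted p = 0.00586 and 0.0112). Oas1a (1.01) also rose and Psmb9 (-0.73) and Isg15 (-0.62) fell, all named after their values were seen. In the heat shock list 5 of 14 genes rose and 0 fell by the limma test, including the inducible chaperone genes Hspa1a (2.51 ± 0.58), Hspa1b (2.33 ± 0.47) and Hsph1 (0.82 ± 0.19), with adjusted p-values from 0.0149 to 0.0281. Hspa8 (0.37) and Hspb1 (1.22) were the other members, named after their values were seen, and 5 rose over the list alone. The calls of Oasl1, Hspa1a, Hspa1b and Hsph1 were lost without the 2 mice with lower control features (adjusted p = 0.0624 to 0.125). Leaving out 1 mouse ended the call of Hspa1a for mutant replicate 2 and wild type replicates 1, 3 and 4 (adjusted p = 0.0580 to 0.0680), and of Hsph1 for mutant replicates 1 and 2 and wild type replicates 1, 3 and 4 (adjusted p = 0.0538 to 0.0768).

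In the unfolded protein and amino acid stress list 3 of 19 genes rose and 2 fell. Asns, the asparagine synthetase gene, rose by 2.98 ± 0.29 (adjusted p = 0.00110), the stress transcription factor gene Atf3 rose by 1.13 ± 0.21 (adjusted p = 0.0106), and the chaperone gene Calr fell by 0.69 ± 0.17 (adjusted p = 0.0287). Creld2 (0.83) rose and Hsp90b1 (-0.51) fell, both named after their values were seen. The cell cycle list had 4 of 23 genes higher and 2 lower. Cdkn1a rose by 3.79 ± 0.61 (13.8-fold, adjusted p = 0.00635), the cyclin gene Ccna2 rose by 1.24 ± 0.18 (adjusted p = 0.00392), and the mitotic kinase gene Wee1, a known clock target, fell by 1.54 ± 0.23 (adjusted p = 0.00486). Ccnb2 (0.74) and Top2a (0.83) also rose and Mcm2 (-0.50) also fell, named after their values were seen. Over the list alone 3 stress genes rose and 4 fell, and 5 cell cycle genes rose and 2 fell. None of the interferon, heat shock, stress and cell cycle lists was called by camera (adjusted p = 0.599, 0.251, 0.894 and 0.166). The cell cycle list was called without the 2 mice with lower control features and with the control features as a covariate, and the heat shock list with that covariate, without rows that follow the control features and without mutant replicate 4, while with an estimated correlation over all mice both had adjusted p = 0.773. Calr and Wee1 lost their calls without the 2 mice with lower control features (adjusted p = 0.0833 and 0.0589), and Calr also without any one of mutant replicates 2 to 4 or wild type replicates 3 and 4 (adjusted p = 0.0549 to 0.0782).

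Most markers of resident liver macrophages rose. Of 12 measured Kupffer cell and macrophage genes 10 rose and 0 fell by the limma test, with 11 rising over the list alone. The scavenger receptor gene Cd163 rose by 1.52 ± 0.20, the complement receptor gene Vsig4 by 1.17 ± 0.15 and the Kupffer cell lectin gene Clec4f by 1.13 ± 0.17 (adjusted p = 0.00316, 0.00288 and 0.00451). The list lay higher by camera (adjusted p = 6.18e-06), with adjusted p = 0.391 with an estimated correlation. Stab1 was the only one of 13 endothelial genes that rose (0.64 ± 0.14). Among 15 stellate cell and fibroblast genes 4 rose, including Col1a1 (1.12 ± 0.25), Col3a1 (0.86 ± 0.19) and Lum (0.54 ± 0.12), with Col1a2 (0.59) as the fourth, and Lrat (-0.45) fell, the last 2 named after their values were seen. Single members rose among 8 cholangiocyte genes (Sox9, 0.88 ± 0.19), 13 lymphocyte genes (Cd79a, 1.65 ± 0.35) and 9 neutrophil genes (S100a8, 1.26 ± 0.34). Among 6 erythroid genes Klf1 and Alas2 fell (-0.95 ± 0.16 and -0.49 ± 0.11). Over the list alone the same counts were 1 endothelial, 5 higher and 1 lower stellate, 1 cholangiocyte, 1 lymphocyte, 0 neutrophil and 2 erythroid. None of these 6 lists was called by camera (adjusted p = 0.166 to 0.980), and for cholangiocytes the median (-0.13) differed in sign from the mean (0.04) and the test. The endothelial list was called without mutant replicate 3 and with the control features as a covariate, and the neutrophil list without mutant replicate 1, with adjusted p = 0.690 and 0.545 with an estimated correlation over all mice. None of the 3 Col3a1 probes (0.41, 1.61 and 0.55) and 1 of the 3 Col1a1 probes passed alone. Without the 2 mice with lower control features Stab1, Col1a1, Col3a1, Lum, Sox9, Cd79a, S100a8 and Alas2 no longer passed (adjusted p = 0.0690 to 0.246). Leaving out 1 mouse ended the calls of S100a8 (6 of 8 mice), Alas2 (5), Stab1 (3), Col1a1 (3), Lum (2), Sox9 (2) and Cd79a (1), with adjusted p = 0.0512 to 0.108.

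The hepatocyte markers that passed were all lower. Of 15 hepatocyte identity genes 3 fell, namely Ttr (-0.71 ± 0.11), Cebpa (-0.59 ± 0.13) and Apoc3 (-0.45 ± 0.11), and albumin, Alb, differed by -0.06 (adjusted p = 0.73). Of 11 pericentral genes 3 fell, namely Oat (-1.32 ± 0.25), Cyp1a2 (-0.60 ± 0.14) and Gulo (-0.51 ± 0.13), and of 7 periportal genes 2 fell, namely Otc (-0.70 ± 0.09) and Hsd17b13 (-0.62 ± 0.11). The counts over the list alone were also 3, 3 and 2, and camera called none of the 3 lists (adjusted p = 0.660, 0.0906 and 0.113). For hepatocyte identity the median (0.07) differed in sign from the mean (-0.02) and the test. Among 12 male-biased liver genes 3 rose, namely C6 (1.28 ± 0.11), Cyp7b1 (1.10 ± 0.23) and Egfr (0.76 ± 0.15), with 6 higher and 1 lower over the list alone, and the list lay higher by camera (adjusted p = 0.0362, and adjusted p = 0.545 with an estimated correlation). Among 13 female-biased genes 2 fell, namely Cyp2a4 (-2.88 ± 0.28) and Atp6v0d2 (-1.21 ± 0.22), 2 also over the list alone, with no call by camera (adjusted p = 0.847), and the median (0.10) differed in sign from the mean (-0.04) and the test. Of 4 sex chromosome transcripts Kdm5d fell (-0.56 ± 0.12) and Xist differed by 0.60 ± 0.24 (adjusted p = 0.135), and 1 was higher and 2 were lower over the list alone. None of the 4 Xist probes passed when tested singly. The call of the male-biased list was lost without mutant replicate 2 (adjusted p = 0.0787) or wild type replicate 1 or 4 (adjusted p = 0.162 and 0.0501). Cebpa, Apoc3, Oat, Cyp1a2, Gulo, Hsd17b13, Cyp7b1, Egfr and Kdm5d no longer passed without the 2 mice with lower control features (adjusted p = 0.0777 to 0.184). Leaving out 1 mouse ended the calls of Gulo (7 of 8 mice), Apoc3 (6), Cyp1a2 (5), Kdm5d (3), Cebpa (2) and Cyp7b1 (1), with adjusted p = 0.0509 to 0.0918.

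**Figure D3:**
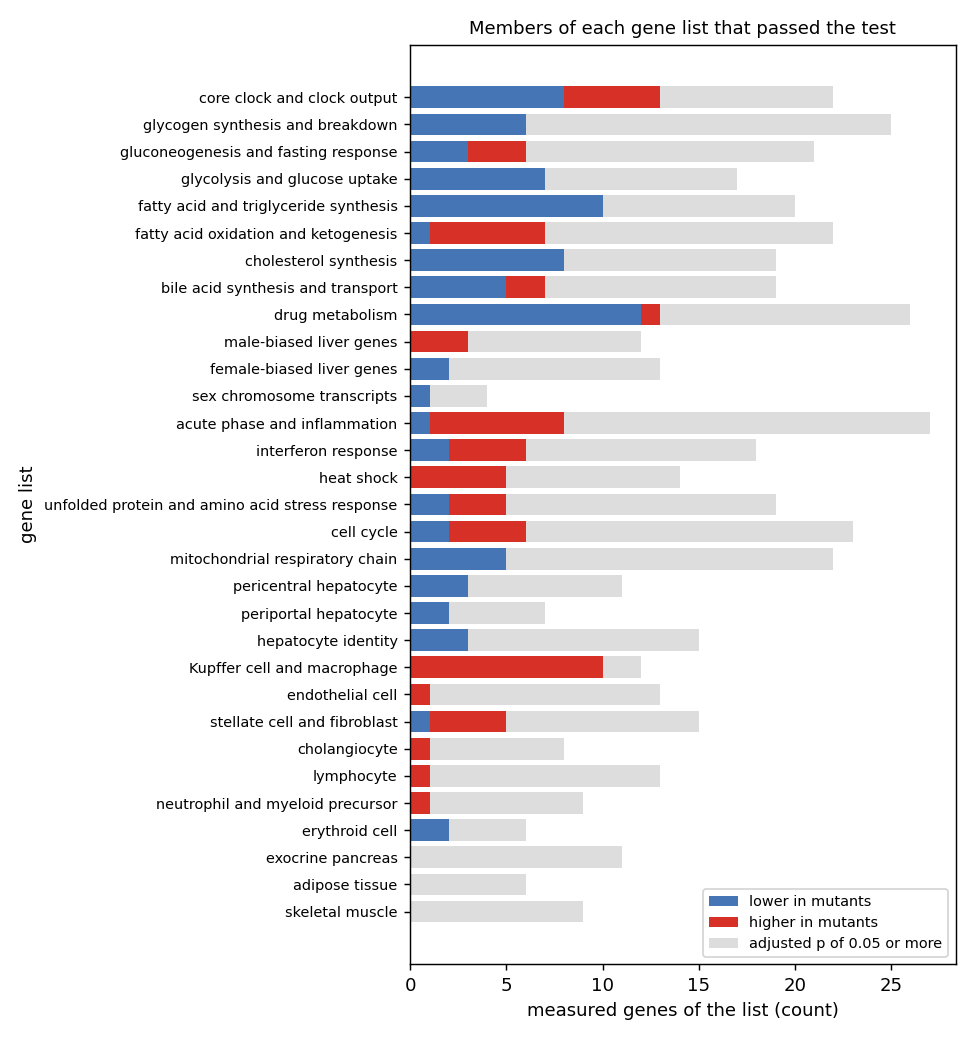
Number of measured genes in each of the 31 gene lists (horizontal axis) that were lower in the mutants, higher in the mutants, or had an adjusted p of 0.05 or more (bar colours), by list (vertical axis). The longest lower bars are drug metabolism (12 genes) and fatty acid and triglyceride synthesis (10 genes), and the longest higher bar is Kupffer cell and macrophage (10 genes).

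In all, 11 of the 30 lists tested by camera were called, 3 higher and 8 lower, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. Of the 35 ways to divide the 8 arrays into 4 and 4, 9 called as many lists, the real one included. The eighth list called lower was skeletal muscle (adjusted p = 0.000777, and adjusted p = 0.545 with an estimated correlation), although 0 of its 9 genes passed by limma over all genes and 9 passed over the list alone. Its median per mouse ran from -3.38 to 0.51 in the mutants and from -0.37 to 2.37 in wild type, so the groups overlapped. The actin gene Acta1 differed by -3.07 ± 0.97, Tnni2 by -3.01 ± 0.97 and Ckm by -2.98 ± 0.97 (adjusted p = 0.0736 to 0.0799). Medians of the 11 exocrine pancreas genes ran from -5.59 to 1.44 in mutants and from -2.52 to 3.39 in wild type. Clps (-2.20 ± 1.90), Cela1 (-1.72 ± 1.39) and Amy2a5 (-1.25 ± 0.86) did not pass, nor did Adipoq (-1.51 ± 0.73), Plin1 (-1.29 ± 0.63) and Lep (-0.79 ± 0.42) among 6 adipose genes. In these last 2 lists 0 genes passed, over all genes or over the list alone, and neither was called by camera (adjusted p = 0.121 and 0.258). The pancreas list was called as deposited, with array weights, and without mutant replicate 4 or wild type replicate 1 or 2, with adjusted p = 0.773 with an estimated correlation over all mice.

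Of the 10 largest falls, all but Sugct were in genes known from squamous or cornified epithelium, a grouping made after the values were seen. The falls were -7.32 ± 0.68 for Crct1 (adjusted p = 0.000907), -6.58 ± 0.71 for the keratin gene Krt4 (adjusted p = 0.00151) and -6.49 ± 0.68 for the cornified envelope gene Lce1d (adjusted p = 0.00138). Calml3, Lce3f, Asprv1, Krt78, Krt15 and Krtdap differed by -6.15 to -5.49, with adjusted p-values from 0.00161 to 0.00220. Within the wild-type group these genes varied widely, and Krt4 ranged from 2.22 to 5.90, against -3.02 to -2.23 in the mutants. The remaining gene of the 10 largest falls was Sugct, a glutarate CoA-transferase gene, which fell by 5.76 ± 0.18 (54.3-fold, adjusted p = 3.07e-05), with an SD of 0.30 in mutants and 0.19 in wild type (n = 4 each). Among the largest rises, Dct, a gene of melanin synthesis, averaged 5.47 ± 0.40 (adjusted p = 0.000398), but 1 of its probes differed by 9.71 and the other by 1.24 without passing (adjusted p = 0.0676). Cxcl14 rose by 3.64 ± 0.19, the histone methyltransferase gene Setdb2 by 3.47 ± 0.35, the gastrin gene Gast by 3.45 ± 0.29 and the ferritin receptor gene Scara5 by 3.38 ± 0.43, with adjusted p-values from 0.000109 to 0.00259. Xlr5a (3.41 ± 0.94, adjusted p = 0.0473) completed the 10 largest rises, and its call was lost without any one of 7 of the 8 mice.

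**Figure D4:**
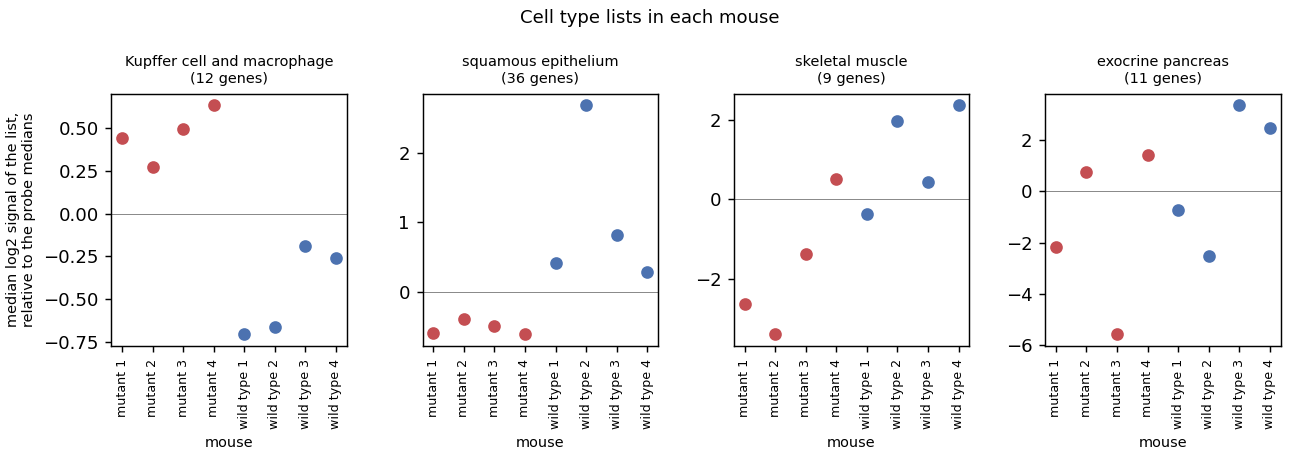
Median log2 signal of 4 cell type lists in each mouse, relative to the probe medians after scaling of the arrays (vertical axes, each panel with its own range), with mutants in red and wild type in blue (horizontal axes). The macrophage list separates the groups, at 0.27 to 0.64 in mutants and -0.71 to -0.19 in wild type, and the squamous list, written after the values were seen, is highest in wild type replicate 2 (2.70), while the skeletal muscle and pancreas lists vary within both groups.

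No excess of changed genes was detected beside Per2 on chromosome 1. Among the 100 measured genes on each side of Per2, 74 of 200 (37.0%) had an unadjusted limma p under 0.05, against 33.6% of the remaining 19287 genes (odds ratio 1.16, 95% confidence interval 0.857 to 1.56, two-sided Fisher's exact test, p = 0.328). Of 15494 windows of that size, 3881 held as many such genes. The odds ratio was 1.43 without wild type replicate 1 (Fisher's exact test, p = 0.0139). It lay below 1 with 50 genes on each side and with the control features as a covariate. It also did so with probes tested singly, where each gene was represented by its least favourable probe.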

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

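The tests of squamous genes, control features and Per2 probes were chosen after the results were seen. In 13 of 256 groups of 4 mice 1 value lay far from the other 3 (by Dixon's ratio), against 12.8 expected by chance. In mutant replicate 1 these were Krt4 (-2.226, others -3.019 to -2.921), Wee1 (-1.226, others -0.557 to -0.424), Apoc3 (-0.091, others -0.364 to -0.329), Cd4 (1.912, others 0.143 to 0.307) and Lep (0.164, others -0.32 to -0.238). In mutant replicate 4 Col3a1 was high (0.661, others 0.175 to 0.236). In wild type replicate 1 Tef was high (1.509, others 0.451 to 0.566), and in replicate 2 Col3a1 was low (-0.988, others -0.412 to -0.339). In wild type replicate 3 Lyve1 was low (-1.622, others -0.36 to -0.15) and the median of the cholesterol synthesis list was high (0.475, others 0.189 to 0.212). In wild type replicate 4 Abcc3 (0.129, others 0.752 to 0.821), Wee1 (0.392, others 0.961 to 1.07) and Cyp1a2 (0.066, others 0.411 to 0.479) were low.

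Squamous epithelial genes were lower in the mutants, with 16 of 36 members of a list written after the values were seen passing and 0 higher. Control features were lower on wild type replicates 2 and 3, yet the squamous list medians were higher there (2.70 and 0.82). In wild type replicates 1 and 4 these medians were 0.42 and 0.28. A lower background on replicates 2 and 3 is therefore argued against as a source of the lower mutant values. Without these 2 mice the passing members had a median of -3.16 (-4.05 with all). As these members were chosen for passing with all mice, that median adds no test of its own. Crct1 read 2.96 and 3.35 in wild type replicates 1 and 4, whose control features lay at 0.13 and -0.03, against -3.32 to -2.98 in the mutants. Over the 4 wild-type arrays the passing members had a mean pairwise correlation across arrays of 0.97, which does not tell 1 source present in different amounts from a genotype effect that varied between mice. Carry-over of squamous epithelium into wild-type samples stays open: the 30 measured members outside the 10 largest falls had a median of -0.81. Krt5 differed by -3.92 and Krt14 by 0.10 (adjusted p = 0.885), but Krt14 read 1.37 in wild type replicate 2 and -0.82 to -0.18 in the other wild-type mice. Members that did not pass went both ways in replicate 2. Evpl read 2.83 and Aqp3 2.57 there, while Ivl (-0.95) and Sprr2d (-0.91) were low, as were the control features (-0.66). A difference in the livers themselves by genotype was not tested and stays open as well.

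The control features lay 0.30 higher in the mutants as a median over all arrays, and the difference was -0.0409 without wild type replicates 2 and 3, which follows from how those 2 arrays were picked and tests no explanation. All 11 lists called with 8 mice were also called without these 2, which excludes nothing, since 9 of the 35 divisions of the arrays called as many lists and 0 lists were called with an estimated correlation. After scaling, the control features of wild type replicates 1 and 4 lay at 0.13 and -0.03, against -0.04 to 0.11 in the mutants. They were thus low on 2 arrays and not in wild type as a group. Whether a lower background on those 2 arrays or genotype moved dim mouse genes stays open, because the values carry no levels.

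The 2 Per2 probes differed from each other by 4.24 in their log2 differences. Lower background is argued against as the source, since the smaller of both differences was still 1.63 in size without wild type replicates 2 and 3. That 1 probe lies in the deleted part of the gene is a candidate explanation that stays open, because probe positions were not given. Opposite probes were not particular to Per2. Of the 8511 genes with several probes, 75, Per2 among them, had probes that passed in both directions when tested singly.

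Among the 35 divisions of the 8 arrays into 4 and 4, the real one included, 1 gave as many changed genes (4333, highest other 1) and 1 as many probes by the Student test (12340, highest other 7072). The real division thus stood alone for these counts, and 1 in 35 is the smallest share the design allows. Any other difference that ran with the groups would give the same result. The glycogen count (6) and the clock count (13, Per2's average included) were also reached by 1 division, with 0 as the highest other. As the other divisions called at most 1 of all rows, these 2 counts add no test of their own. As many lists as the 11 called were reached by 9 of the 35 divisions, with 16 as the highest other, for mutant replicates 1 and 2 with wild type replicates 3 and 4. The odds ratio around Per2 (1.16) was reached by 16 of the 35, with 2.36 as the highest other. Chance cannot be excluded for the number of lists or for that odds ratio.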

How the results depend on the processing

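The fits as deposited, without wild type replicates 2 and 3 and with the control features as a covariate were chosen after seeing the data. The cause was not tested for any of the changes below, and some of the fits had fewer mice. Of the 94 named genes that passed, 57 passed and 92 kept their direction in every setting run for them, the exceptions being Per2 and Egfr with single probes. Of the 94, 11 were not tested in the setting without rows that follow the control features. Without wild type replicates 2 and 3, 32 lost their call, in a fit with fewer mice where their differences were 0.799 to 1.17 times those with all mice (median 0.941), and with the covariate 29 lost it. Of the 3441 named genes changed, 1285 (37.3%) were still called without these 2 mice, and all 3441 kept their direction.

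With each probe on its own, genes changed between genotypes numbered 6702 as probes and 4085 were lower, 8 clock genes passed, the lower Per2 probe was -1.70, at least 1 probe did not pass for Calr, Dct, Gulo, Hsd17b13, Sdha, Sox9 and Tef, 1 Egfr probe was -0.0855 (adjusted p = 0.915) and the odds ratio around Per2 was 0.801. In that setting a clock gene counted as passing only if all its probes passed in the same direction. The odds ratio there took, for each gene, the probe that differed least in the direction of the averaged difference. With averaged probes the odds ratio around Per2 was 0.885 with 50 genes on each side and 0.969 with the covariate. As deposited, 1537 rows were lower. Lists called were 0 with an estimated correlation, 11 by the directional form of fry, of which 10 were also called by camera, and 25 by the mixed form of fry. Fry tests a list against no change and camera tests it against other genes, so their calls answer different questions.

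Without wild type replicates 2 and 3, genes changed between genotypes numbered 1766 as rows (879 higher, 887 lower), 5 clock genes passed and Per2 was 0.44 (adjusted p = 0.138). With the covariate they numbered 2229 (914 higher, 1315 lower), 7 clock genes passed and Per2 was 0.41 (adjusted p = 0.116).

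With the replicate block, which takes mice with the same number as a pair, 2030 rows changed (1011 higher, 1019 lower), 5 clock genes passed and Per2 was 0.42 (adjusted p = 0.112). The numbers are not known to pair the mice: deviations of mice with the same number correlated across genes at -0.103 to 0.0983, and the own number was the best partner in 2 of 4.

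Leaving out 1 mouse gave 2884 to 3696 genes changed between genotypes as rows, 1314 to 1703 higher and 1542 to 1993 lower, 7 to 11 clock genes, 5 to 8 glycogen genes, 10 to 13 lists, 10585 to 16302 probes by the Student test, Per2 at 0.36 to 0.46 and an odds ratio of 1.11 to 1.43. The highest odds ratio, without wild type replicate 1, had p = 0.0139 by Fisher's exact test. The bile acid list lost its call without rows that follow the control features, and the male-biased list with array weights and with the block. The pericentral list was called with each probe on its own and without mutant replicate 2, and the periportal list with each probe on its own. With an estimated correlation over all mice both had adjusted p = 0.545 by camera. By directional fry the periportal list was called (adjusted p = 0.0259) and the skeletal muscle list was not (adjusted p = 0.0803). A filter on dim rows, the choice of the brightest probe and a variance trend were not run, because the values carry no levels.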

Other observations

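The tissue lists and genes of this paragraph were chosen after the values were seen. Genes of the glandular stomach were high in single mice: Tff2, a mucosal peptide gene, read 6.42 and 5.40 in mutant replicates 1 and 4, and Gkn3 read 6.29 and 5.56, while neither passed between genotypes (adjusted p = 0.250 and 0.137). Of the 12 stomach genes Tff1 (2.33 ± 0.37) and Muc6 (1.08 ± 0.19) rose and 0 fell by limma. The median of these 12 ran from 0.02 to 0.81 in the mutants and from -0.68 to -0.15 in wild type. The median of 11 intestinal genes was 3.55 in mutant replicate 4 and -0.78 to 0.10 in the other 7 mice, and Lct rose (1.43 ± 0.39) and Fabp2 fell (-1.19 ± 0.18). Lct read -1.24 and -1.05 in wild type replicates 2 and 3, against -0.05 and -0.34 in replicates 1 and 4. Of 8 smooth muscle genes 0 rose and Actg2 (-0.59 ± 0.16) and Synm (-2.33 ± 0.38) fell by limma. The median of these 8 ran from -0.35 to -0.06 in the mutants and from 0.05 to 0.43 in wild type. Myh11 (-0.04) and Myl9 (-0.27) did not pass. Synm read highest in wild type replicates 2 and 4 (2.02 and 1.78), which also had the highest skeletal muscle medians (1.96 and 2.37). Its fall may thus share the source of that signal, which was not tested.

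Some genes differed widely with little spread within groups, and these were also chosen after their values were seen. Slc22a29 (-4.29 ± 0.18), Ppp1r42 (-4.78 ± 0.27), Ptprg (-3.72 ± 0.24) and Slc26a4 (-3.92 ± 0.30) were lower in the mutants, and Glp1r (3.33 ± 0.15), the receptor gene for glucagon-like peptide, was higher.

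The test of clock phase was chosen after the result was seen. A difference in clock phase between the groups may underlie the clock gene changes: of 16 clock genes other than Arntl, 12 differed in the direction given by their usual phase relative to Arntl, and the 10 that passed all followed it. These 16 included Wee1 of the cell cycle list and left out Bhlhe40 (-0.63), Cry2 (-0.82) and Per2, which passed in the clock list. Nr1d1 (0.12), Per3 (0.25), Npas2 (-0.21) and Rora (-0.22) went the other way without passing. With 1 sampling time per mouse, a change of phase cannot be told from a change of level. Segments of different parental strain could place strong changes side by side, and 17 pairs of the 200 strongest genes lay within 10 genes of each other, against a median of 19 in 10000 random sets (5th to 95th percentile 12 to 26, permutation p = 0.70). The odds ratio of 1.16 around Per2 (95% confidence interval 0.857 to 1.56) leaves a segment around Per2 open too.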
